A study of Mus musculus with 12 samples.

How the data were processed

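Whole-number counts of reads per gene were deposited by the authors as a single table of raw, unnormalised counts, per the file header and its values. Per the submitters' processing notes, bcl2fastq, Trimmomatic 0.32 and TopHat2 2.1.1 were used with genome build GRCm38; the counting program, its annotation release and its use of strand are not given in the sources used here. Overlapping, antisense and pseudogene counts are therefore uncertain. The table holds 31060 versioned gene identifiers, of which 25042 match the GENCODE M21 names with their version and 30875 without it. Of 12 labelled samples, 11 have a column whose name matches them. The double mutant sample numbered 4 was not analysed here, and 1 column of the table, named like an Akita library numbered 3, matches no sample label and was not used in any step. Whether that column holds the double mutant sample numbered 4 is not stated, so Akita has n = 2 here. Nothing in the labels says that samples of a group came from separate animals, so p-values measure the spread between these samples. No pair of libraries in a group agreed within counting noise (lowest chi-square per gene 17.2).

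Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, which kept 15630 genes, TMM factors, one fit of all 4 groups, glmQLFit with robust=TRUE and glmQLFTest, with Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 difference is its size over the square root of F. The plan did not state the robust setting of the dispersion trend; its default was set after call counts had been seen, and the other setting gave the same 6 counts. Each of 6 comparisons was written before the data were examined, as were the gene lists, of which 25 were tested and 1, of sex-linked genes, served as a check of the samples. Eif2s3y, a gene of the Y chromosome, was at 61.7 to 82.5 CPM in all 11 libraries. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 25 lists of a comparison; no list call in any comparison held with an estimated correlation, and fry called 6 of 62. Values in brackets after the name of a list are its median log2 difference and its camera adjusted p. DESeq2 1.42.0 was an alternative. CPM values use TMM factors, and levels are given as mean ± SD.

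Genes named in the text followed a rule written before the data were examined: Tet2, Ins2, Gm14005, Bcl2l11, Il6, Tnf, Il1b and Il1r1; per comparison up to 10 higher and 10 lower called genes with an absolute log2 difference of at least 1 and a mean of at least 1 CPM, by smallest p, leaving out symbols made of Gm or Rik and digits; for a called list up to 4 members, by smallest p and highest mean; and counts of 5 or fewer in full. Gbp2b, Pcna and Pax5 and the genes of the replicate block were named after their values were seen. Alternatives were RLE and upper quartile factors, DESeq2, limma voom, no low count filter, a mean of at least 5 CPM, the replicate number as a block, both groups alone, robust=FALSE and each library left out; leaving out all libraries numbered 3 and the robust dispersion trend were added after seeing the data. A sign change of a gene called in neither fit was counted only where both values lay over 1 standard error from 0.

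Replicate numbers come from the labels, which do not say what they mark. Deviations from group means of same-numbered libraries correlated at 0.485 to 0.791 between WT and Tet2het, 0.340 to 0.589 between WT and the double mutant and 0.318 to 0.533 between Tet2het and the double mutant, all over 0.1, so the numbers were treated as pairing these 3 groups. Libraries numbered 1 and 2 of different groups correlated at up to 0.691 as well. Only 4 of 9 libraries were closest to one of their own number, those numbered 3 among them. Deviations cancel out within a group, so a number 3 that stands apart puts numbers 1 and 2 on the same side. Correlations over 0.1 therefore do not show that numbers 1 and 2 pair, and the replicate block rests on that assumption. Akita libraries did not meet the pairing rule (-0.351 and 0.0661 with WT). The replicate block was still fitted to all libraries, so Akita numbers 1 and 2 shared the blocks of those numbers. The rule needed 3 pairs, so a group of 2 libraries could not meet it, and the deviations of such a group mirror each other.

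The tests of genes were tested on simulated data drawn from the real means and library sizes with genes changed by known folds. For Tet2het against WT, 1 of 66 genes changed 2-fold, 32 of 66 changed 4-fold and 48 of 65 changed 8-fold were called; for Akita against WT these were 2 of 66, 19 of 65 and 35 of 66, and for the double mutant against WT 1 of 66, 28 of 66 and 48 of 65. Of the genes left unchanged, 3, 1 and 3 were called in these comparisons, beside the changed genes that were called. The real data gave 4, 0 and 7 calls. No simulation without changed genes was run, so the false calls to be expected among so few calls are not known. Changes of 2-fold were thus rarely detectable with this spread. In a simulation with 1 raised list and genes drawn independently, that list was called, and so was 1 of the 24 unchanged lists. It cannot show how often lists are called falsely where their members vary together, so it gives no false call rate for the real lists.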

Results

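RNA-seq counts per gene were compared in lineage-negative bone marrow cells from C57BL/6 mice of 4 genotypes. This fraction is what is left of marrow after cells with markers of mature blood lineages are removed, and it is enriched for stem and progenitor cells. The groups were wild type (WT, n = 3), mice with 1 disrupted copy of Tet2 (labelled Tet2het, n = 3), mice heterozygous for the Akita allele of the insulin gene Ins2 (Akita, n = 2) and mice labelled as carrying both (Tet2het_Akita, here the double mutant, n = 3). Tet2 encodes an enzyme that oxidises 5-methylcytosine in DNA. The Akita allele is dominant, and its misfolded product damages pancreatic beta cells and gives high blood glucose. Total counts were 19228500, 19903212 and 14814409 for WT replicates 1 to 3 and 20711259, 16815487 and 20413130 for Tet2het. They were 16795242 and 19722471 for Akita and 20642121, 22600405 and 17138242 for the double mutant. A gene at 0 counts can lie as high as the level of 3 counts per library, which covers counting error only. On raw totals that level is 0.133 to 0.203 CPM (counts scaled to library size). The other CPM values use TMM factors, so they are on another scale than this range. A double mutant sample numbered 4 was not analysed here.

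Tet2 (ENSMUSG00000040943.12; GRCm38 chromosome 3, 133463679 to 133545139, minus strand, protein coding) was read first, as a check of the labels. It stood at 91.2, 128 and 45.1 CPM in the WT libraries and 19, 18.5 and 19.3 CPM in those labelled Tet2het. It stood at 131 and 107 CPM in Akita and 66.5, 108 and 34.2 CPM in those labelled double mutant. Within a library number, Tet2het was at 20.8%, 14.5% and 42.8% of WT and the double mutant at 72.9%, 84.2% and 75.7%. The Tet2het against WT difference did not pass the edgeR quasi-likelihood test over all genes (log2 difference -2.22, SE 0.45, adjusted p = 0.505). It passed by DESeq2 (adjusted p = 0.00181) and, without the libraries numbered 3, by edgeR (-2.55, adjusted p = 0.0162). Tet2 in the double mutant against Tet2het was not called without the replicate block (log2 difference 1.88, SE 0.45, adjusted p = 0.140) and was called higher with it (1.70, adjusted p = 0.0286). Tet2het and the double mutant share a Tet2 label, yet Tet2 lay further below WT in Tet2het within every library number. The level of Tet2 thus does not bear out that shared label, and these values do not say in which of both groups it is in doubt. Every direction below is therefore one between libraries carrying these labels. No value for Ins2 was used here, so the Akita label has no such check.

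**Figure D1:**
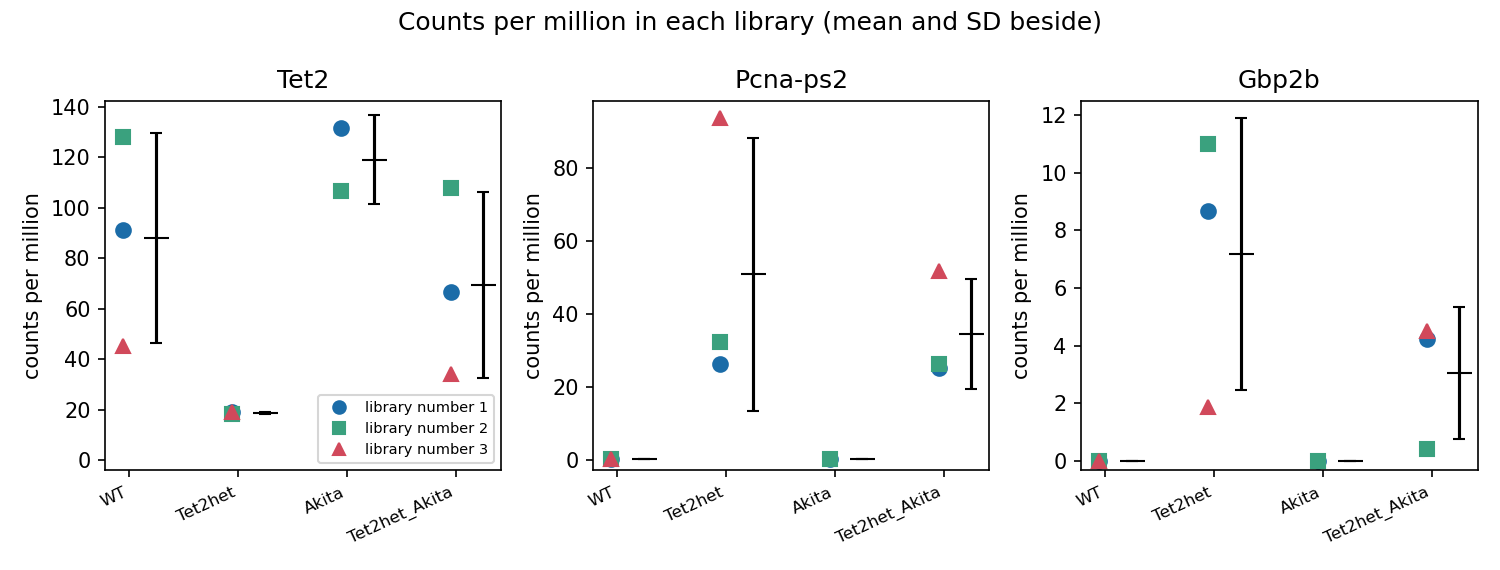
CPM (y axis, linear) of Tet2, the pseudogene Pcna-ps2 and Gbp2b in each of the 11 libraries by labelled genotype (x axis), with colour and shape giving the library number and bars the mean and SD of each group. Tet2 lies at 19, 18.5 and 19.3 CPM in the Tet2het libraries and at 66.5, 108 and 34.2 CPM in the double mutant. Pcna-ps2 is at 0.353, 0.249 and 0.363 CPM in WT.

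The libraries numbered 3 of WT, Tet2het and the double mutant stood apart from numbers 1 and 2, and no Akita sample is labelled with that number. A column named like an Akita library numbered 3 matches no sample label and was not used. In number 3 against the mean of numbers 1 and 2, the erythroid list (genes of red cell precursors) had a median log2 difference of 1.56 in WT, 2.38 in Tet2het and 1.65 in the double mutant. The neutrophil primary granule list (Mpo, Elane and other enzymes of early granulocytes) was at -2.33, -3.45 and -0.66. The maturing neutrophil list was at -2.57, -2.07 and 0.17. Numbers 1 and 2 also differed from each other in the erythroid list. Its mean log2 CPM minus that of all libraries was 0.43, -0.77 and 1.05 in WT replicates 1 to 3. It was -0.35, -1.96 and 0.15 in the double mutant, so number 1 lay nearer to 3 than to 2 in both groups. In Tet2het it was -0.30, 0.11 and 1.92. Mitochondrially encoded genes took 3.43%, 4.46% and 9.76% of counts in the 3 libraries numbered 3 and 1.36% to 1.94% in the 8 others. Values without the libraries numbered 3, an alternative chosen after seeing the data, stand beside the results.

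The effect of the Tet2 label alone was read from Tet2het against WT. Of 15630 genes tested, 4 were called, and all 4 were processed pseudogenes that were higher in Tet2het. Pcna-ps2 (ENSMUSG00000067608.4; chromosome 19, 9283380 to 9284160) had 7, 5 and 6 counts in WT and 558, 546 and 1945 in Tet2het (adjusted p = 0.00524). Atp6v0c-ps2 (ENSMUSG00000080242.5; chromosome 6, 37806086 to 37806550) had 2, 2 and 1 counts in WT and 574, 829 and 610 in Tet2het (adjusted p = 6.18e-04). Gm9825 had 0, 1 and 0 counts in WT and 245, 447 and 909 in Tet2het (adjusted p = 0.0115). Gm14292 had 0, 0 and 0 counts in WT and 56, 83 and 96 in Tet2het (adjusted p = 0.0451). Counts of such copies are uncertain, because reads can be shared with the parent gene. The parent Pcna was at 334 ± 35.2 CPM (SD, n = 3) in WT and 357 ± 102 in Tet2het, so a change in its level does not account for Pcna-ps2. All 4 calls go with the Tet2 label, and whether they follow from Tet2 itself was not tested. With the replicate block 8 genes were called. The naming rule applied to that fit, after its values were seen, added Rps2-ps10, Eif3j2 and, lower, Fcnb, a ficolin of the granulocyte lineage (-3.79, adjusted p = 0.00135). Without the libraries numbered 3 the count was 22 (16 higher, 6 lower), by DESeq2 45 (30 higher, 15 lower) and with only both groups in the fit 2. It was 1 without WT replicate 1, 1 without WT replicate 2, 1 without WT replicate 3, 7 without Tet2het replicate 3 and 7 without double mutant replicate 3.

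Of the 25 gene lists, 7 were called by camera in Tet2het against WT, with no member called over all genes or adjusted over the list alone. The oxidative phosphorylation list rose, with 28 of 28 members above 0 (median log2 difference 0.24, adjusted p = 1.59e-07), a call lost at adjusted p = 0.803 with an estimated correlation. The medians of B lineage (0.41, adjusted p = 5.67e-04), T and NK cell (0.27, adjusted p = 0.0110), interferon response (0.15, adjusted p = 0.0211) and erythroid (0.26, adjusted p = 0.0236) rose, each with adjusted p = 0.803 with an estimated correlation. Neutrophil primary granule (-0.61, adjusted p = 0.0211) and basophil, mast cell and eosinophil (-0.36, adjusted p = 0.0236) fell, both with adjusted p = 0.803 with an estimated correlation. The 6 libraries make 10 splits, of which 9 called at least 7 lists, the real split included. Vpreb1, part of the surrogate light chain of pre-B cells, was at 1.67 ± 0.564 CPM in WT and 3.59 ± 1.22 in Tet2het (log2 difference 1.10, SE 0.41, adjusted p = 1). Mpo was at 4678 ± 3189 CPM in WT and 3748 ± 2984 in Tet2het (log2 difference -0.32, SE 0.82, adjusted p = 1). With the libraries numbered 3 left out, 4 of the 7 calls held. Erythroid then had a median of -0.02, interferon response a median of 0.074 and basophil, mast cell and eosinophil a median of 0.24. Without Tet2het replicate 3 the neutrophil primary granule list was called in the opposite direction (median 0.53, adjusted p = 0.0281). Neutrophil primary granule was not called, with the median in brackets, without WT replicate 1 (-0.25) or WT replicate 2 (-0.12). Erythroid was not called without WT replicate 2 (-0.27) or Tet2het replicate 3 (-0.58). B lineage was not called without Tet2het replicate 2 (0.20). T and NK cell was not called without WT replicate 3 (-0.04), Tet2het replicate 1 (0.35) or Tet2het replicate 2 (0.05). Basophil, mast cell and eosinophil was not called without WT replicate 3 (-0.24) or Tet2het replicate 3 (0.04). Interferon response was not called without WT replicate 1 (0.14), WT replicate 3 (0.09), Tet2het replicate 1 (0.15), Tet2het replicate 2 (0.10) or Tet2het replicate 3 (0.15). Oxidative phosphorylation was not called without Tet2het replicate 3 (0.07). Neutrophil primary granule stayed called with a median moved by over 1.5 times, to -1.35 without WT replicate 3, -1.19 without Tet2het replicate 1 and -1.11 without Tet2het replicate 2. Erythroid stayed called at 0.82 without WT replicate 3, 0.82 without Tet2het replicate 1 and 0.59 without Tet2het replicate 2. T and NK cell stayed called at 0.58 without WT replicate 1 and 0.53 without Tet2het replicate 3. Interferon response stayed called at 0.31 without WT replicate 2. Oxidative phosphorylation stayed called at 0.15 without WT replicate 2, 0.45 without WT replicate 3 and 0.42 without Tet2het replicate 1.

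The effect of the Akita allele alone was read from Akita against WT. No gene was called by edgeR, limma voom or DESeq2. An unadjusted p under 0.05 was found for 67 of 15630 genes by edgeR, 48 by voom and 92 by DESeq2. These counts are far below a share of 0.05 of the genes, the share to be expected with no change at all. The tests were thus conservative here, and the lack of calls does not show that no gene changed. Camera called 7 lists, with no member called. The medians of maturing neutrophil (0.74, adjusted p = 1.18e-05), neutrophil primary granule (0.73, adjusted p = 0.00208), insulin signalling and FOXO targets (0.30, adjusted p = 0.0302) and unfolded protein response (0.20, adjusted p = 0.0302) rose, each with adjusted p = 0.863 with an estimated correlation. Oxidative phosphorylation (-0.24, adjusted p = 1.00e-06), megakaryocyte and platelet (-0.44, adjusted p = 0.00173) and monocyte and macrophage (-0.28, adjusted p = 0.0302) fell, each with adjusted p = 0.863 with an estimated correlation. Ngp, a granule protein of maturing neutrophils, was at 4122 ± 3211 CPM in WT (SD, n = 3) and 6211 ± 2634 in Akita (n = 2), by edgeR with log2 difference 0.59, SE 1.05, adjusted p = 1. WT replicate 3 has no labelled Akita counterpart. Without the libraries numbered 3, 2 of the 7 calls held, those of megakaryocyte and platelet and of monocyte and macrophage. Maturing neutrophil then had a median of -0.02 (adjusted p = 0.466). Neutrophil primary granule was not called, with the median in brackets, without WT replicate 3 (-0.07) or Akita replicate 1 (0.57). Maturing neutrophil was not called without WT replicate 3 (-0.03) or Akita replicate 1 (0.45). Monocyte and macrophage was not called without WT replicate 3 (-0.20), Tet2het replicate 1 (-0.28), Tet2het replicate 3 (-0.28) or Akita replicate 2 (0.04). Oxidative phosphorylation was not called without WT replicate 3 (-0.03). Insulin signalling and FOXO targets was not called without WT replicate 3 (-0.05) or Akita replicate 2 (0.23). Unfolded protein response was not called without WT replicate 3 (-0.02) or Akita replicate 1 (0.08). Neutrophil primary granule stayed called with a median moved by over 1.5 times, to 1.15 without WT replicate 2. Maturing neutrophil stayed called at 1.12 without WT replicate 1, 1.15 without WT replicate 2 and 1.30 without Akita replicate 2. Megakaryocyte and platelet stayed called at -0.28 without WT replicate 3. Oxidative phosphorylation stayed called at -0.36 without WT replicate 2. Insulin signalling and FOXO targets stayed called at 0.46 without WT replicate 2. Unfolded protein response stayed called at 0.34 without WT replicate 2 and 0.36 without Akita replicate 2.

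The double mutant was first compared with WT. The B lineage, dendritic cell and T and NK cell lists fell and the maturing neutrophil list rose by camera. None of these calls was kept when the correlation was estimated: in that order they had adjusted p = 0.118, 0.162, 0.194 and 0.162 with an estimated correlation. Of 7 genes called, 3 were lower. Fam129c was at 26.7 ± 4.21 CPM in WT and 4.64 ± 0.437 in the double mutant (log2 difference -2.52, SE 0.28, adjusted p = 0.0175; SD, n = 3). Akap12, a scaffold for protein kinase A, was at 14.3 ± 2.12 and 1.54 ± 0.716 CPM (log2 difference -3.20, SE 0.39, adjusted p = 0.0234). Chst3, a chondroitin sulfotransferase, was at 14.8 ± 2.89 and 1.30 ± 0.692 CPM (log2 difference -3.50, SE 0.42, adjusted p = 0.0234). The 4 higher were Pcna-ps2, Atp6v0c-ps2, Gm9825 and Gm14292, the pseudogenes also called in Tet2het against WT. With the replicate block 255 genes were called (144 higher, 111 lower), among them all 7. The naming rule applied to that fit, after its values were seen, gave among the higher the Fc receptor gene Fcgr4 (2.65, adjusted p = 0.00299) and the acute phase gene Saa3 (4.63, adjusted p = 0.0180). Among the lower it gave Spib, a transcription factor of B and plasmacytoid dendritic cells (-2.61, adjusted p = 0.0115), and Bach2, a transcriptional repressor in B cells (-2.14, adjusted p = 0.00865). Without the libraries numbered 3 the count was 519, by DESeq2 408 (267 higher, 141 lower), by voom 13 and with no low count filter 52. Upper quartile factors gave 4 higher and 6 lower. The count was 1 without WT replicate 1, 1 without WT replicate 2, 1 without WT replicate 3, 4 without Tet2het replicate 1, 11 without Tet2het replicate 2, 49 without Tet2het replicate 3, 21 without double mutant replicate 1 and 2 without double mutant replicate 3.

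Camera called 12 lists in the double mutant against WT. The B lineage list fell, with 16 of 18 members below 0 (median log2 difference -2.16, adjusted p = 4.82e-21). It had adjusted p = 0.118 with an estimated correlation. None of its members was called over all genes, 14 were lower adjusted over the list alone, and 10 were called lower with the replicate block. Its medians within library numbers 1 to 3 were -1.99, -2.44 and -1.83. Its smallest p-values were those of Igll1, part of the surrogate light chain (log2 difference -2.76, SE 0.41, adjusted p = 0.0666), and Blk, a B cell kinase (log2 difference -2.59, SE 0.38, adjusted p = 0.0666). The dendritic cell list fell (median log2 difference -1.39, adjusted p = 6.48e-14) and had adjusted p = 0.162 with an estimated correlation. Adjusted over the list alone, 12 of its 15 members were lower, and Clec9a, a receptor of cross-presenting dendritic cells, had a log2 difference -2.38, SE 0.41, adjusted p = 0.0779. T and NK cell (-1.13, adjusted p = 2.33e-09) and erythroid (-1.17, adjusted p = 4.08e-04) fell as well, with adjusted p = 0.194 and 0.702 with an estimated correlation. Adjusted over the list alone, 12 of 20 T and NK cell genes and 0 of 21 erythroid genes were lower. Maturing neutrophil rose with 26 of 26 members above 0 (median 2.57, adjusted p = 6.46e-24) and had adjusted p = 0.162 with an estimated correlation. Of its members, 13 were higher adjusted over the list alone, and its medians by library number were 1.24, 1.81 and 4.66. Maturing neutrophil stayed called with a median moved by over 1.5 times, to 1.69 without WT replicate 3. S100a9, a calcium binding protein of neutrophils, was at 4297 ± 3249 CPM in WT and 17142 ± 4764 in the double mutant (adjusted p = 0.592).

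Other lists that rose were glycolysis (0.69, adjusted p = 1.18e-05), proinflammatory cytokine and NF-kB (0.49, adjusted p = 4.07e-05) and immediate early (0.50, adjusted p = 9.52e-04), by their median log2 differences. In that order they had adjusted p = 0.162, 0.390 and 0.162 with an estimated correlation. Plasma cell (0.86, adjusted p = 0.00560), neutrophil primary granule (0.88, adjusted p = 0.00793) and oxidative stress response (0.18, adjusted p = 0.0257) rose too. In that order these had adjusted p = 0.390, 0.702 and 0.162 with an estimated correlation. Ldha, which makes lactate, was at 443 ± 73.5 CPM in WT and 735 ± 152 in the double mutant (log2 difference 0.73, SE 0.22, adjusted p = 0.284). Jchain, which links antibody subunits, was at 969.8 ± 247 and 1826 ± 312 CPM (log2 difference 0.91, SE 0.29, adjusted p = 0.331). The basophil, mast cell and eosinophil list fell (-0.41, adjusted p = 0.0408), with adjusted p = 0.702 with an estimated correlation. It was not called with the replicate block (adjusted p = 0.103). With the libraries numbered 3 left out, 11 of the 12 calls held and plasma cell did not (median 0.35, adjusted p = 0.391). Of the 10 splits of these 6 libraries, 5 called at least 12 lists, the real split included. Neutrophil primary granule was not called, with the median in brackets, without WT replicate 3 (0.05) or double mutant replicate 2 (0.72). Erythroid was not called without WT replicate 3 (-0.59) or double mutant replicate 2 (-0.34). Plasma cell was not called without WT replicate 3 (0.46) or double mutant replicate 3 (0.63). Basophil, mast cell and eosinophil was not called without WT replicate 1 (-0.53), WT replicate 3 (-0.48), Tet2het replicate 3 (-0.42), double mutant replicate 1 (0.00) or double mutant replicate 2 (-0.42). Oxidative stress response was not called without WT replicate 2 (0.19) or double mutant replicate 2 (0.13). The other 7 lists were called with each of the 11 libraries left out. Neutrophil primary granule stayed called with a median moved by over 1.5 times, to 1.41 without WT replicate 2. Plasma cell stayed called at 0.51 without double mutant replicate 1. Basophil, mast cell and eosinophil stayed called at -0.68 without WT replicate 2 and -1.08 without double mutant replicate 3. The list proinflammatory cytokine and NF-kB stayed called at 0.76 without WT replicate 1, 0.83 without WT replicate 2 and 0.76 without double mutant replicate 3. Glycolysis stayed called at 0.40 without WT replicate 3. Oxidative stress response stayed called at 0.29 without double mutant replicate 3. Immediate early stayed called at 0.28 without WT replicate 3 and 0.32 without double mutant replicate 3.

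**Figure D2:**
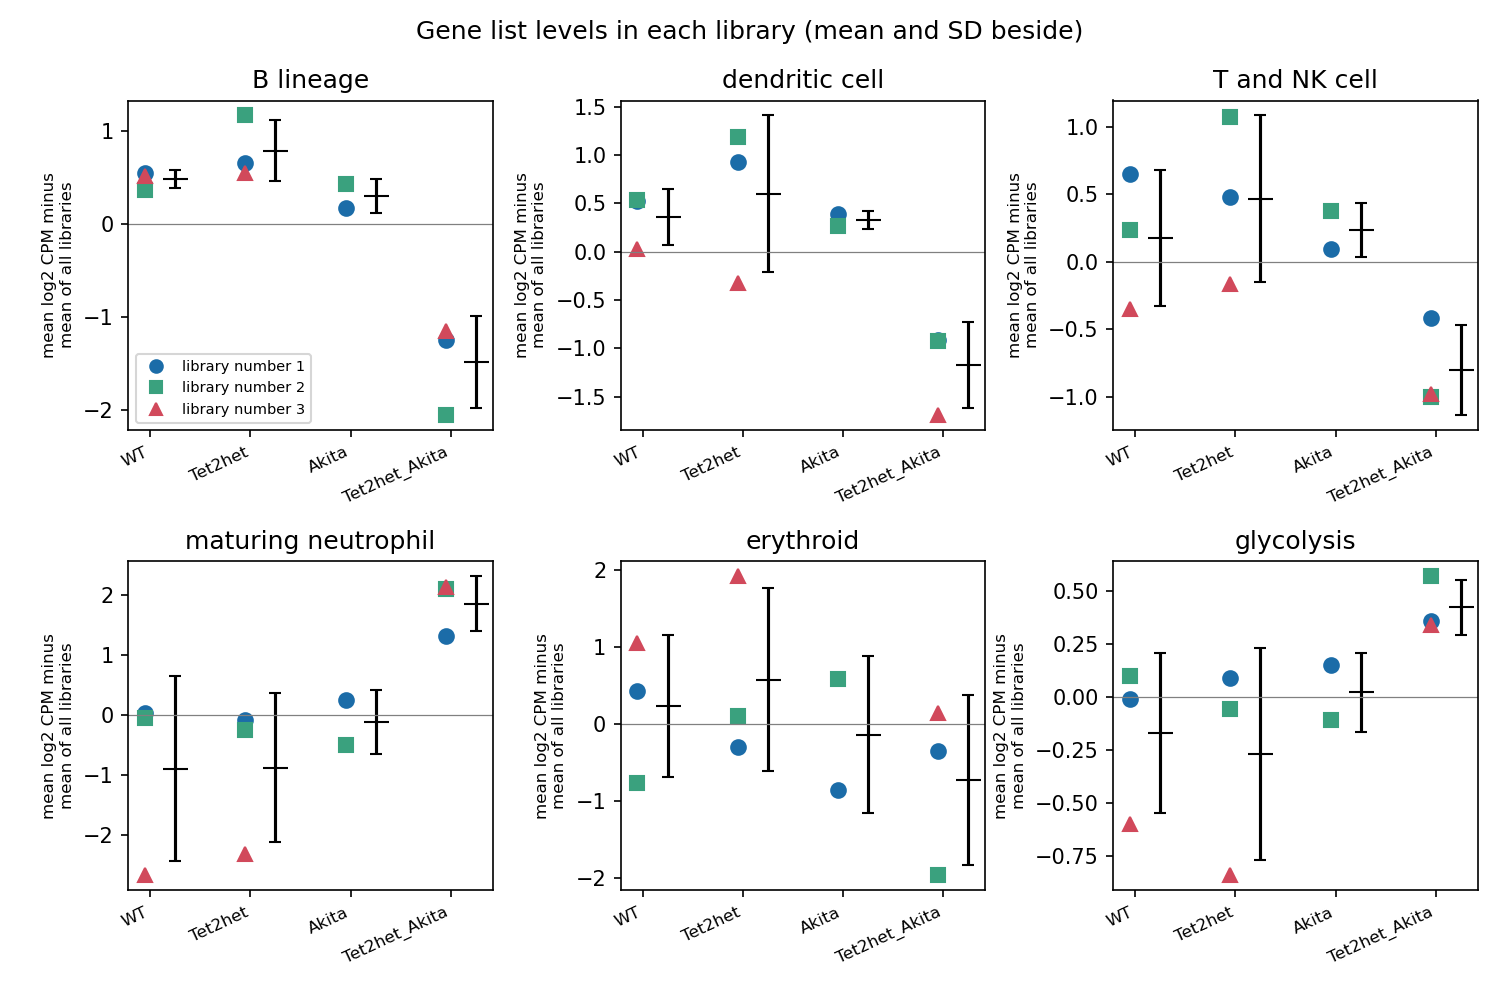
Mean over list members of log2 CPM minus the mean of all 11 libraries (y axis, log2 units) for 6 gene lists in each library by labelled genotype (x axis), with colour and shape giving the library number and bars the mean and SD of each group. The 3 double mutant libraries are the lowest for B lineage, whose median against WT is -2.16. The median difference of number 3 from the mean of numbers 1 and 2 in the erythroid list is 1.56 in WT and 2.38 in Tet2het. In WT, number 1 lies nearer to number 3 than to number 2 in that list.

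The Akita allele on the Tet2het background was read from the double mutant against Tet2het, where 41 genes were called, 13 higher and 28 lower. Genes of the B lineage were among the lower. Ebf1, a transcription factor that commits cells to that lineage, was at 19.8 ± 7.42 CPM in Tet2het and 1.87 ± 0.736 in the double mutant (log2 difference -3.40, SE 0.43, adjusted p = 0.0322; SD, n = 3). Spib (log2 difference -3.06, SE 0.36, adjusted p = 0.0259), Igll1 (log2 difference -3.43, SE 0.41, adjusted p = 0.0259) and Fcrla (log2 difference -2.78, SE 0.34, adjusted p = 0.0259) were lower. So were Blk, Fam129c, Akap12, Chst3 and Lynx1, with log2 differences of -2.82, -2.94, -3.56, -3.59 and -2.36, and Klhl14, which lay under the level of 3 counts in the double mutant libraries. Among the higher, Mmp25, a membrane metalloproteinase of neutrophils, was at 8.81 ± 4.27 CPM in Tet2het and 118 ± 34.5 in the double mutant (log2 difference 3.74, SE 0.60, adjusted p = 0.0460). Slfn4, an interferon-inducible myeloid gene, was at 43.4 ± 8.92 and 519.7 ± 189.7 CPM (log2 difference 3.58, SE 0.57, adjusted p = 0.0460). Nfkbiz, an inducible regulator of NF-kB, was at 239 ± 37.7 and 565 ± 80.2 CPM (log2 difference 1.24, SE 0.19, adjusted p = 0.0384). Clu (2.98), Neat1 (1.22), Dhrs9 (2.81), Rhoj (3.76) and Ighg1 (4.89) were higher by their log2 differences, as were Entpd3 at 0.223 ± 0.0253 and 13.7 ± 12.6 CPM and Stfa1 at 0.0644 ± 0.112 and 23.8 ± 19.9 CPM. With the replicate block 703 genes were called (442 higher, 261 lower), among them all 41. Without the libraries numbered 3 the count was 1163, by DESeq2 538 (305 higher, 233 lower), with no low count filter 86, with the strict filter 8 and with both groups alone 0, against 1701 genes at an unadjusted p under 0.05 in edgeR with all groups. It was 0 without WT replicate 1, 0 without WT replicate 2, 1 without Tet2het replicate 1, 1 without Tet2het replicate 2, 66 without Tet2het replicate 3, 0 without Akita replicate 1, 0 without Akita replicate 2, 8 without double mutant replicate 1, 3 without double mutant replicate 2 and 6 without double mutant replicate 3.

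Camera called 14 lists in this comparison. B lineage fell (-2.62, adjusted p = 1.61e-21) and had adjusted p = 0.107 with an estimated correlation. Of its 18 members 7 were called lower over all genes and 15 adjusted over the list alone, and its medians by library number were -1.93, -3.43 and -1.74. Dendritic cell fell (-1.60, adjusted p = 2.39e-12) and had adjusted p = 0.253 with an estimated correlation. Over all genes 2 of its 15 members, Spib and Klk1, were called, and 11 adjusted over the list alone. T and NK cell (-1.30, adjusted p = 1.02e-11), erythroid (-1.35, adjusted p = 3.56e-06), oxidative phosphorylation (-0.26, adjusted p = 0.00143) and cell cycle (-0.23, adjusted p = 0.00881) fell. Respectively, they had adjusted p = 0.253, 0.512, 0.662 and 0.760 with an estimated correlation. Maturing neutrophil rose (2.27, adjusted p = 3.43e-18) and had adjusted p = 0.284 with an estimated correlation. Over all genes 2 of its 26 members, Mmp25 and Stfa1, were called, and 11 adjusted over the list alone. Neutrophil primary granule (1.53, adjusted p = 8.52e-05), glycolysis (0.71, adjusted p = 1.26e-05) and proinflammatory cytokine and NF-kB (0.75, adjusted p = 5.09e-04) rose. Respectively, they had adjusted p = 0.543, 0.253 and 0.498 with an estimated correlation. Plasma cell (1.05, adjusted p = 0.00143), unfolded protein response (0.35, adjusted p = 0.00529), immediate early (0.38, adjusted p = 0.0119) and hematopoietic stem cell (0.29, adjusted p = 0.0441) rose. In that order these had adjusted p = 0.299, 0.642, 0.297 and 0.558 with an estimated correlation. The stem cell list was not called with the replicate block (adjusted p = 0.0635) and had a median of -0.22 without the libraries numbered 3. Of the 14 calls 11 held without those libraries, where immediate early was not called (median 0.13, adjusted p = 0.257). The cell cycle list was then called in the opposite direction (median 0.20, adjusted p = 0.0210). Hematopoietic stem cell was not called, with the median in brackets, without Tet2het replicate 3 (-0.05), Akita replicate 1 (0.31), Akita replicate 2 (0.31) or double mutant replicate 3 (-0.11). Neutrophil primary granule was not called without Tet2het replicate 3 (0.36). Proinflammatory cytokine and NF-kB was not called without Tet2het replicate 3 (0.26). Oxidative phosphorylation was not called without Tet2het replicate 3 (-0.03) or double mutant replicate 1 (-0.18). Unfolded protein response was not called without Tet2het replicate 3 (0.03) or double mutant replicate 2 (0.10). Cell cycle was not called without Tet2het replicate 3 (0.08) or double mutant replicate 3 (-0.25). Immediate early was not called without Tet2het replicate 3 (0.32) or double mutant replicate 3 (0.22). Hematopoietic stem cell stayed called with a median moved by over 1.5 times, to 0.50 without Tet2het replicate 2, 0.47 without double mutant replicate 1 and 0.57 without double mutant replicate 2. Maturing neutrophil stayed called at 1.33 without Tet2het replicate 3. Erythroid stayed called at -0.67 without Tet2het replicate 3 and -0.73 without double mutant replicate 2. Plasma cell stayed called at 0.58 without Tet2het replicate 2. Glycolysis stayed called at 0.39 without Tet2het replicate 3. Oxidative phosphorylation stayed called at -0.41 without Tet2het replicate 1. Unfolded protein response stayed called at 0.67 without double mutant replicate 3. Cell cycle stayed called at -0.40 without Tet2het replicate 1 and -0.46 without Tet2het replicate 2.

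The Tet2 label on the Akita background was read from the double mutant against Akita. Akap12 was at 18 ± 3.96 CPM in Akita (SD) and 1.54 ± 0.716 in the double mutant (log2 difference -3.54, SE 0.41, adjusted p = 0.0327). Chst3 was at 15.9 ± 3.28 and 1.30 ± 0.692 CPM (log2 difference -3.61, SE 0.44, adjusted p = 0.0413) and Fam129c at 22.4 ± 3.40 and 4.64 ± 0.437 CPM (log2 difference -2.27, SE 0.30, adjusted p = 0.0475). These and, higher, Pcna-ps2, Atp6v0c-ps2 and Gm9825 made up the 6 calls. Of 11 lists called, B lineage (-2.11, adjusted p = 8.08e-18), dendritic cell (-1.43, adjusted p = 1.01e-12), T and NK cell (-1.11, adjusted p = 1.03e-08) and erythroid (-0.64, adjusted p = 0.0383) fell. These had adjusted p = 0.172, 0.185, 0.291 and 0.782 with an estimated correlation, and 13 of 18 B lineage members were lower adjusted over the list alone. Maturing neutrophil (1.73, adjusted p = 2.09e-14), glycolysis (0.38, adjusted p = 3.48e-04), immediate early (0.38, adjusted p = 3.71e-04) and oxidative phosphorylation (0.22, adjusted p = 0.00184) rose. These had adjusted p = 0.296, 0.291, 0.185 and 0.782 with an estimated correlation. Proinflammatory cytokine and NF-kB (0.34, adjusted p = 0.00690), oxidative stress response (0.28, adjusted p = 0.0152) and plasma cell (0.61, adjusted p = 0.0152) rose. These had adjusted p = 0.745, 0.185 and 0.522 with an estimated correlation. Without the libraries numbered 3, 436 genes were called and 9 of the 11 lists held. Oxidative phosphorylation (adjusted p = 0.141) and plasma cell (adjusted p = 0.247) did not. Erythroid was not called, with the median in brackets, without Tet2het replicate 2 (-0.64), Akita replicate 2 (0.11) or double mutant replicate 2 (0.04). Plasma cell was not called without Akita replicate 2 (0.19) or double mutant replicate 3 (0.49). Proinflammatory cytokine and NF-kB was not called without double mutant replicate 2 (0.27). Oxidative phosphorylation was not called without double mutant replicate 3 (0.08). Oxidative stress response was not called without double mutant replicate 2 (0.35). Erythroid stayed called with a median moved by over 1.5 times, to -1.32 without Akita replicate 1 and -1.28 without double mutant replicate 3. Glycolysis stayed called at 0.66 without Akita replicate 1. By DESeq2 the count of genes was 189 (125 higher, 64 lower), by voom 3, with upper quartile factors 3 (2 higher, 1 lower) and with RLE factors 5 (3 higher, 2 lower). It was 20 with no low count filter, 3 with the strict filter and 1 with both groups alone. It was 1 without WT replicate 1, 1 without WT replicate 2, 1 without WT replicate 3, 11 without Tet2het replicate 3, 0 without Akita replicate 1, 1 without Akita replicate 2, 0 without double mutant replicate 2 and 1 without double mutant replicate 3, beside 1032 genes at an unadjusted p under 0.05 in edgeR with all 11 libraries.

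Whether the Akita effect differed between the Tet2 backgrounds was tested with the interaction. No gene was called by edgeR, where 537 had an unadjusted p under 0.05, or by voom, where 511 did. Both counts are below a share of 0.05 of the genes tested, so the lack of calls does not show that no gene differed. DESeq2 called 60, a fit with no low count filter 3 and a fit without the libraries numbered 3 called 7. Of 11 lists called by camera, B lineage had the lowest median (-2.43, adjusted p = 8.07e-26), with adjusted p = 0.0656 with an estimated correlation. Adjusted over the list alone 12 of its 18 members were lower, and Ebf1 had a log2 difference -3.48, SE 0.59, adjusted p = 0.401. Dendritic cell (-1.64, adjusted p = 1.45e-13), T and NK cell (-1.18, adjusted p = 1.90e-12) and erythroid (-0.99, adjusted p = 8.10e-04) lay below 0. The 3 had adjusted p = 0.254, 0.254 and 0.585 with an estimated correlation. Maturing neutrophil (1.42, adjusted p = 2.08e-11), glycolysis (0.54, adjusted p = 2.02e-04), plasma cell (0.72, adjusted p = 0.00277) and immediate early (0.48, adjusted p = 0.00551) lay above 0. Respectively, they had adjusted p = 0.377, 0.315, 0.364 and 0.315 with an estimated correlation. Proinflammatory cytokine and NF-kB (0.45, adjusted p = 0.0201), megakaryocyte and platelet (0.56, adjusted p = 0.0212) and monocyte and macrophage (0.47, adjusted p = 0.0328) lay above 0 as well. These had adjusted p = 0.585, 0.585 and 0.585 with an estimated correlation. Of the 11 calls 9 held without the libraries numbered 3. Megakaryocyte and platelet then had a median of -0.29 (adjusted p = 0.332) and monocyte and macrophage a median of 0.25 (adjusted p = 0.576). Monocyte and macrophage was not called, with the median in brackets, without WT replicate 3 (0.69), Tet2het replicate 3 (-0.18), Akita replicate 2 (0.18), double mutant replicate 1 (0.30) or double mutant replicate 2 (0.26). Erythroid was not called without WT replicate 2 (-0.38), Tet2het replicate 3 (-0.08), Akita replicate 2 (-0.30) or double mutant replicate 2 (-0.31). Megakaryocyte and platelet was not called without WT replicate 3 (0.39), Tet2het replicate 1 (0.48), Tet2het replicate 3 (0.41) or double mutant replicate 3 (-0.03). Plasma cell was not called without Akita replicate 2 (0.20). Proinflammatory cytokine and NF-kB was not called without WT replicate 1 (0.23), WT replicate 2 (0.21), Tet2het replicate 3 (-0.20) or double mutant replicate 2 (0.21). Glycolysis was not called without Tet2het replicate 3 (0.29). Immediate early was not called without WT replicate 2 (0.23) or Tet2het replicate 3 (0.27). Maturing neutrophil stayed called with a median moved by over 1.5 times, to 0.91 without WT replicate 1, 0.88 without WT replicate 2, 2.35 without WT replicate 3, 0.47 without Tet2het replicate 3 and 0.91 without Akita replicate 2. Monocyte and macrophage stayed called at 0.91 without Tet2het replicate 1, 0.78 without Tet2het replicate 2, 0.77 without Akita replicate 1 and 0.73 without double mutant replicate 3. Erythroid stayed called at -1.54 without Tet2het replicate 1 and -1.72 without Akita replicate 1. Megakaryocyte and platelet stayed called at 0.30 without Akita replicate 2 and 0.85 without double mutant replicate 2. Plasma cell stayed called at 0.36 without Tet2het replicate 1 and 1.12 without Tet2het replicate 3. The list proinflammatory cytokine and NF-kB stayed called at 0.78 without WT replicate 3. Glycolysis stayed called at 0.82 without WT replicate 3 and 0.83 without Tet2het replicate 1. Immediate early stayed called at 0.32 without WT replicate 1 and 0.27 without double mutant replicate 3.

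Cytokine genes and the long noncoding RNA gene Gm14005 (Morrbid; ENSMUSG00000074813.12; chromosome 2, 128178319 to 128502765) were fixed for reading in every comparison. Gm14005 lies near Bcl2l11, the gene of the proapoptotic protein BIM. Tnf was at 48 ± 2.83 CPM in WT, 45.1 ± 9.05 in Tet2het, 45.2 ± 9.99 in Akita and 120.5 ± 29.2 in the double mutant. It was not called in the double mutant against WT (log2 difference 1.33, SE 0.24, adjusted p = 0.0880) or Tet2het (log2 difference 1.42, SE 0.24, adjusted p = 0.0545). With the replicate block it was called in both (1.33, adjusted p = 0.0367, and 1.42, adjusted p = 0.0223). Gm14005 was at 7.13 ± 4.08 CPM in WT and 14.8 ± 5.85 in the double mutant (log2 difference 1.05, SE 0.79, adjusted p = 0.816). With the libraries numbered 3 left out this difference was 0.93 and passed (adjusted p = 0.0410). A higher level in numbers 1 and 2 was not particular to the double mutant (16.2 and 19.9 CPM). Gm14005 was there at 9.32 and 9.66 CPM in WT, 14.1 and 16.1 in Tet2het and 11 and 9.12 in Akita. In number 3 it was at 2.42 CPM in WT, 1.26 in Tet2het and 8.43 in the double mutant. Bcl2l11 was at 146 ± 87.8 CPM in WT and 139 ± 69.6 in the double mutant (log2 difference -0.07, SE 0.64, adjusted p = 0.991). Il6 was at 65.8 ± 23 and 39.8 ± 31 CPM (adjusted p = 0.833), Il1b at 28.7 ± 11 and 52.5 ± 23.8 (adjusted p = 0.610) and Il1r1 at 9.23 ± 1.19 and 14 ± 6.84 (adjusted p = 0.763). Within each library number Il1b was higher in Tet2het as well (50, 54.9 and 33 CPM) than in WT (35.6, 34.7 and 16 CPM). With all 11 libraries and no block, edgeR called none of these genes in the 6 comparisons.

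Log2 differences on both backgrounds were set against each other across 15630 genes, which are not independent replicates, in pairs of comparisons that share no library. For the Akita effect, Pearson r was 0.221 and Spearman rho 0.359; 0 and 41 genes were called and none was shared. It was 0.0581 with the replicate block, 0.114 without the libraries numbered 3, 0.0343 with no low count filter and 0.386 with the strict filter. It was -0.0791 without Tet2het replicate 3, 0.00101 without WT replicate 3, 0.0183 without Akita replicate 1 and 0.413 without double mutant replicate 3. For the Tet2 effect, r was 0.356 and rho 0.146, and r was 0.0876 with no low count filter. It was 0.227 without Tet2het replicate 3 and 0.213 without double mutant replicate 3. Of its 4 and 6 called genes 3 were shared, Pcna-ps2, Atp6v0c-ps2 and Gm9825, all higher, against 7.68e-04 for independent lists. These 3 pseudogenes are also read below as marks of the Tet2 line, so sharing them does not show an effect of Tet2 itself. Of 100 random groupings of the 11 libraries, 42 and 56 gave a correlation of mean log2 CPM differences at least as far from 0 as the real groups (0.340 and 0.259).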

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

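The tests of neutrophil dilution, of the libraries numbered 3, of composition, of descent from the Tet2 line and of depth were chosen after the values they measure had been seen; those of gene length and of other splits were not. By the camera test of the interaction, 11 lists were called for an Akita effect that differs between the labelled Tet2 backgrounds. The groups that share the Tet2 label did not share a Tet2 level, so the interaction does not isolate the Akita effect. None of these 11 lists held with an estimated correlation. Their median log2 interactions, with the lowest and highest value with 1 library left out where any moved by over 1.5 times, were -2.43 for B lineage, -1.64 for dendritic cell, -1.18 for T and NK cell, -0.99 for erythroid (-1.72 without Akita replicate 1 to -0.08 without Tet2het replicate 3), 1.42 for maturing neutrophil (0.47 without Tet2het replicate 3 to 2.35 without WT replicate 3), 0.72 for plasma cell (0.20 without Akita replicate 2 to 1.12 without Tet2het replicate 3), 0.56 for megakaryocyte and platelet (-0.03 without double mutant replicate 3 to 0.85 without double mutant replicate 2), 0.54 for glycolysis (0.29 without Tet2het replicate 3 to 0.83 without Tet2het replicate 1), 0.48 for immediate early (0.23 without WT replicate 2 to 0.63 without Tet2het replicate 1), 0.47 for monocyte and macrophage (-0.18 without Tet2het replicate 3 to 0.91 without Tet2het replicate 1) and 0.45 for proinflammatory cytokine and NF-kB (-0.20 without Tet2het replicate 3 to 0.78 without WT replicate 3).

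The first pattern is lower B lineage and dendritic cell genes with higher maturing neutrophil genes in the libraries labelled double mutant. Neutrophil RNA diluting all other RNA alike would lower stem cell genes as far. Yet the B lineage median against WT lay below the hematopoietic stem cell median by a difference of -2.60 (18 and 23 genes). The permutation p was 1e-05, the smallest the resamples can give, across genes that are not independent. B lineage was picked after its fall had been seen, so this p-value is not that of a list fixed beforehand. Within library numbers 1 to 3 the medians against WT were 0.28, -0.24 and 0.79 for stem cell genes. Those of B lineage were -1.99, -2.44 and -1.83. The libraries numbered 3 are not the whole source, since without them the B lineage median was -2.29, that of dendritic cell -1.65 and that of maturing neutrophil 1.47. A change in the cells of the lineage-negative fraction, whether from genotype or from how well lineage-positive cells were removed, stays open and was not tested.

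The 6 libraries of a pair of groups make 10 splits, too few for a share under 0.05. The real split called 4 genes in Tet2het against WT (highest other 0; 1 of 10 splits as large), 7 in the double mutant against WT (highest other 0; 1 of 10) and 41 in the double mutant against Tet2het (highest other 3; 1 of 10). With the replicate block, the 3 other splits that part every pair called 0 genes in each comparison, against 8, 255 and 703. These are fewer still, so they cannot give a share under 0.05 either. Each other split mixes libraries of both groups, so a real difference between the groups adds to its spread and lowers its calls. Lists behaved otherwise: 9 of 10 splits called at least the real 7 lists in Tet2het against WT (highest other 11), 5 of 10 at least the real 12 in the double mutant against WT (highest other 15) and 1 of 10 the real 14 in the double mutant against Tet2het (highest other 13).

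The second pattern is Tet2, at 19, 18.5 and 19.3 CPM in the libraries labelled Tet2het and 66.5, 108 and 34.2 CPM in those labelled double mutant. On the Tet2het side cell composition is argued against, because without the libraries numbered 3 the lowest list median in Tet2het against WT was -0.30 while Tet2 was at -2.55 (SE 0.26). On the double mutant side it stays open. Against Tet2het the highest list median, of maturing neutrophil, was 2.27 and Tet2 was at 1.88 (SE 0.45). Without the libraries numbered 3 the highest list median was 1.23 and Tet2 was at 2.22 (SE 0.26). Number 3 against numbers 1 and 2, a single library per group, gave mixed values. In Tet2het it goes against composition, with Tet2 at 0.045 and the maturing neutrophil list at -2.07. In WT Tet2 was lower in number 3 (91.2, 128 and 45.1 CPM) with the list at -2.57. In the double mutant Tet2 was lower in number 3 too (66.5, 108 and 34.2 CPM) with the list at 0.17, so Tet2 did not follow the list there. Double mutant mice from outside the Tet2 line are argued against, since all 4 genes called higher in Tet2het against WT, on chromosomes 2, 6 and 19, were called higher in the double mutant, and Gbp2b, 9.05 Mb from Tet2, had 0 counts in the WT and Akita libraries and 84, 8 and 71 in the double mutant. Gbp2b goes with the label but is not Tet2 itself, so a label wrong for the Tet2 allele, another number of disrupted copies and a true difference in Tet2 transcript stay open.

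The third pattern is the distance of the libraries numbered 3. Depth as the shared source is argued against, as their highest total was 20.4 M counts against a median of 19.8 M counts in the 8 others, though WT replicate 3 had the lowest of all. A shared loss of long transcripts is argued against by correlations of exon length with the number 3 difference of -0.0485 in WT and -0.0169 in Tet2het across genes; in the double mutant it was -0.186. Mitochondrially encoded genes took 3.43%, 4.46% and 9.76% of counts in these libraries of WT, Tet2het and the double mutant against 1.36% to 1.94% in the 8 others, so RNA quality apart from such a shared loss stays open for all 3. No biological explanation was tested, since the labels do not say what a number marks.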

How the results depend on the processing

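Leaving out all libraries numbered 3 and the robust dispersion trend were chosen after the data were seen. For Tet2het against WT, 4 genes became 45 (DESeq2), 8 (replicate block), 2 (only the 2 groups in the fit), 22 (number 3 libraries left out), and 1 to 7 with 1 library left out. For the double mutant against WT, 7 genes became 408 (DESeq2), 13 (limma voom), 52 (no low count filter), 255 (replicate block), 519 (number 3 libraries left out), and 1 to 49 with 1 library left out. For the double mutant against Tet2het, 41 genes became 538 (DESeq2), 86 (no low count filter), 8 (strict low count filter), 703 (replicate block), 0 (only the 2 groups in the fit), 1163 (number 3 libraries left out), and 0 to 66 with 1 library left out. For the double mutant against Akita, 6 genes became 3 (upper quartile factors), 189 (DESeq2), 3 (limma voom), 20 (no low count filter), 3 (strict low count filter), 18 (replicate block), 1 (only the 2 groups in the fit), 436 (number 3 libraries left out), and 0 to 11 with 1 library left out. For the interaction, 0 genes became 60 (DESeq2), 3 (no low count filter), 3 (replicate block), 7 (number 3 libraries left out), and stayed at 0 with any 1 library left out. Akita against WT had 0 genes by edgeR under each alternative run and by DESeq2 and voom. The cause was not tested, except that fits with fewer libraries or without the filter change the spread or the genes tested. At this depth and spread 2-fold changes were rarely recovered in simulation, which did not vary the depth.

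Tet2 in Tet2het against WT (-2.22) kept its direction under all alternatives (-2.54 to -1.85 with 1 library left out) and passed the threshold by DESeq2 (-2.21) and with the libraries numbered 3 left out (-2.55). The correlation of the Akita effect (0.221) was 0.0343 (no low count filter), 0.386 (strict low count filter), 0.0581 (replicate block) and -0.0791 to 0.413 with 1 library left out, the lowest without Tet2het replicate 3. That of the Tet2 effect (0.356) was 0.277 (limma voom), 0.0876 (no low count filter), 0.290 (replicate block), 0.259 (number 3 libraries left out) and 0.213 to 0.393. Of 62 list calls over the 6 comparisons, 0 held with an estimated correlation and 6 by fry. With the replicate block 54 of them were called the same way, and with number 3 left out 46. In Tet2het against WT the lists neutrophil primary granule (-1.35 to 0.53 with 1 library left out), erythroid (-0.58 to 0.82 with 1 library left out) and basophil, mast cell and eosinophil (0.24 with number 3 left out, -0.50 to 0.041 with 1 library left out) changed direction in the camera test. In Akita against WT the lists neutrophil primary granule (-0.057 with number 3 left out, -0.066 to 1.15 with 1 library left out), maturing neutrophil (-0.025 with number 3 left out, -0.034 to 1.30 with 1 library left out), insulin signalling and FOXO targets (-0.0053 with replicate block, -0.037 with number 3 left out, -0.049 to 0.46 with 1 library left out) and unfolded protein response (-0.032 with replicate block, -0.013 with number 3 left out, -0.022 to 0.36 with 1 library left out) changed direction in the camera test. In the double mutant against Tet2het the lists hematopoietic stem cell (-0.22 with number 3 left out) and cell cycle (0.20 with number 3 left out, -0.46 to 0.082 with 1 library left out) changed direction in the camera test. In the double mutant against Akita the list erythroid (-1.32 to 0.11 with 1 library left out) changed direction in the camera test. In the interaction the lists monocyte and macrophage (-0.18 to 0.91 with 1 library left out) and megakaryocyte and platelet (-0.29 with number 3 left out) changed direction in the camera test. Where the direction in that test held and the call was lost, the median crossed 0 for erythroid in Tet2het against WT (-0.022 with number 3 left out), T and NK cell in Tet2het against WT (-0.044 without WT replicate 3), monocyte and macrophage in Akita against WT (0.042 without Akita replicate 2), basophil, mast cell and eosinophil in the double mutant against WT (0.004 without double mutant replicate 1), hematopoietic stem cell in the double mutant against Tet2het (-0.047 without Tet2het replicate 3), hematopoietic stem cell in the double mutant against Tet2het (-0.11 without double mutant replicate 3), megakaryocyte and platelet in the interaction (-0.027 without double mutant replicate 3) and proinflammatory cytokine and NF-kB in the interaction (-0.20 without Tet2het replicate 3). Without WT replicate 3 47 list calls were kept and without Tet2het replicate 3 42. Prss34 in the double mutant against WT reversed with number 3 left out (-1.51). Of 6432 values of named genes under alternatives, 156 changed sign, 0 of them among the 41 called cases. Of these cases, 3 to 32 were still called with 1 library left out. The replicate block kept all 41 called cases; where Akita has 1 library left, it is assumed to vary like the other groups.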

Other observations

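Gbp2b, an interferon-inducible guanylate binding protein gene (ENSMUSG00000040264.10; chromosome 3, 142594847 to 142619179), was chosen after its values were seen. It lies 9.05 Mb from Tet2 on the same chromosome and had 0, 0 and 0 counts in WT, 0 and 0 in Akita, 183, 185 and 39 in Tet2het and 84, 8 and 71 in the double mutant. Pax5, which maintains B cell identity, had 747, 677 and 488 counts in Tet2het and 62, 10 and 39 in the double mutant, and was among the genes called lower there.

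Ighg1, an immunoglobulin constant region gene, was at 13.6 ± 5.02 CPM in Tet2het and 402 ± 297 in the double mutant, a range of 62 to 613 over its 3 libraries. Cd79b, part of the B cell receptor, was at 54.5 ± 28.2 and 16.9 ± 2.19 CPM (SD, n = 3).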
